A study of Mus musculus with 6 samples.

How the data were processed

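RNA was measured by sequencing in whole-tissue brain samples of 6 adult male mice, 3 deficient for Kdm5c and 3 wild-type littermates. Per the labels' protocols, all came from crossing a heterozygous deficient female on a C57BL/6 background to a wild-type 129 male, RNA was purified on silica columns, and libraries were made with an Illumina TruSeq RNA kit. The brain region dissected and the strandedness of the libraries are not given in the sources used here, and neither are the aligner, the counting program and the gene annotation. The submitters' processing notes name DESeq2 and the genome build GRCm38.

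The deposited table holds, per the file headers, one raw count per gene symbol and mouse, which the authors did not normalize: the values are whole numbers and their totals differ between mice. The authors also deposited a mean signal over the 6 mice, and it matched the mean of the counts divided by median-ratio size factors with a largest relative difference of 2.12e-09. A log2 fold change with its standard error, a Wald score and an unadjusted p-value per gene were deposited by the authors too. Compared with the counts, that log2 fold change is wild type over deficient, and it is shrunken, since the largest standard error in the table is 0.144. These columns were used only for comparison, and the tests were run on the counts.

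Of 43346 rows, 22259 had no read in any mouse and 21087 had at least 1. In 27 rows the symbol had been turned into a date; these kept their counts and were not named. Positions, GC content and transcript lengths came from GENCODE M21, which is on GRCm38, by symbol: 39391 of 43344 distinct symbols matched exactly, 926 through a synonym and 3027 not at all. Overlap of exons with other genes was read from the same annotation. Without a stated use of strand, reads from overlapping or antisense genes cannot be told apart. The annotated exons of A930011O12Rik, Baiap3, D1Pas1, Doc2a, Ftx, Hsf2bp, Hspa1a, Kmt2c, Malat1, Meg3, Miat, Mirg, Mpp4, Neat1, Ntn3, Ntng2, Oaz3, Rab3b, Rian, Setd1a, Snhg11, Trf, Trim71, Tspan2, Ttn and Zcwpw1 overlap those of at least 1 other annotated gene, small RNA genes included, so the values of these genes are uncertain to that extent. The counts do not resolve exons, and the labels do not describe the allele.

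Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's default expression filter (minimum count 10, minimum total count 15), which left 15127 genes holding 99.94 to 99.95% of each library's counts. Libraries were scaled by trimmed mean of M-values, and the genotypes were compared by edgeR's quasi-likelihood test with genotype as the only factor. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic, and CPM are counts relative to the scaled library total. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, for lists with at least 5 tested members, adjusted over lists and leaving Kdm5c out. Positions were tested with two-sided Fisher's exact tests.

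The design, the 41 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Kdm5c, then the 12 largest rises and the 12 largest falls among genes with adjusted p under 0.05, without overlap between the genotypes and with a mean of at least 1 CPM. It adds up to 4 members of each list with the smallest p-values, whether or not they pass, and Ntng2, Kdm5d and genes next to Kdm5c. Genes outside the rule are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

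The tests were tested on simulated data, with counts drawn for 15127 genes from these libraries and 50 genes changed at each fold. The main test recovered 30% of genes changed 1.25-fold, 64% at 1.5-fold, 82% at 2-fold and 96% at 4-fold. Of 154 genes called in that simulation 18 had not been changed, which is above the nominal 5%. Each gene was drawn on its own, without shifts shared by many genes of a mouse. Recovery and error in the real data may therefore differ.

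Totals ranged from 20221675 to 24555412 counts, so the libraries were of similar depth. Intervals and floors based on counts cover counting error only. Alternatives were other scalings (median-ratio, upper quartile, none), no filter and a stricter filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, other thresholds and leaving out each mouse. For lists, an estimated correlation and fry were also run. Offsets for GC content and length were added after seeing the data. Pseudocount alternatives had been listed for normalized values and do not apply to counts.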

Results

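Gene expression was measured by RNA sequencing in the brain of 3 adult male mice deficient for Kdm5c and 3 wild-type littermates, to find which transcripts differ when this X-linked gene, which encodes a demethylase of histone H3 lysine 4, is disrupted. The deficient libraries held 21090278, 24178704 and 21945675 counts and the wild-type libraries 24555412, 20221675 and 22956590. No pair of libraries from one genotype agreed within sampling noise. The chi-square per gene between mice of one genotype ran from 3.56 to 17.64, and the highest value was between deficient mice 1 and 2. The first principal component held 49.5% of the variance and placed the deficient mice at -3.6, -34.7 and -14.9 and the wild-type mice at 15.7, 21.7 and 15.8.

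Kdm5c RNA itself was only slightly lower in the deficient brains, and the difference was not past the threshold. Its level was 72.8 ± 6.75 CPM (SD, n = 3) in deficient and 81.5 ± 3.43 CPM (SD, n = 3) in wild-type mice. The log2 fold change was -0.16 ± 0.07 (SE), with an adjusted p of 0.196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test of the CPM values gave p = 0.2, where 0.1 is the smallest value possible for 3 against 3. In the authors' deposited table the log2 fold change, sign turned to deficient over wild type, was -0.1485 with an unadjusted p of 0.0535. The gene lies on chromosome X at 152233020 to 152274535 (GRCm38). Because the counts cover the whole gene and the labels do not describe the allele, this level does not check the genotype labels. Among other genes named in advance, Ntng2, which encodes netrin-G2, had a log2 fold change of 0.13 ± 0.09 (SE, adjusted p = 0.361 by edgeR's quasi-likelihood test). The Y-linked relative Kdm5d had -0.12 ± 0.21 (SE, adjusted p = 0.767 by edgeR), which turned to 0.18 when wild-type mouse 2 was left out, and Iqsec2, next to Kdm5c, had 0.13 ± 0.06 (SE, adjusted p = 0.209 by edgeR).

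Among genes with a mean of at least 1 CPM that passed the test without overlap between genotypes, those that rose most in deficient brain were low in wild-type brain. Pnmt, the enzyme that makes adrenaline from noradrenaline, was 25.5-fold higher, at 4.62 ± 1.91 CPM against 0.179 ± 0.0508 CPM (SD, n = 3 each). Germ cell genes followed: Zar1, known from oocytes, and Tex14, known from the bridges between germ cells, had log2 fold changes of 3.22 ± 0.24 and 3.21 ± 0.17 (SE). Apoc1, an apolipoprotein, rose from 1.90 ± 0.432 to 11.3 ± 0.547 CPM (SD, n = 3 each). The axon guidance receptor Robo3 fell to 7.44 ± 0.700 CPM (SD, n = 3), a log2 fold change of -1.63 ± 0.10 (SE).

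In all, 371 genes were higher and 375 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test, out of 15127 tested, and 3760 had an unadjusted p under 0.05. Large changes were mostly rises: 87 genes were at least 2-fold higher and 21 at least 2-fold lower, while 476 of the 746 changed by less than 1.5-fold. The directions differed in transcript length and GC content: the median longest transcript was 2888.5 nt for higher, 4860 nt for lower and 3403 nt for all tested genes, and the median GC content was 53%, 49% and 49.9%, with values for 98.8% of the changed genes. None of the 746 overlapped between genotypes, which passing the test with 3 against 3 mice all but requires, so it adds no support. Of all tested genes 30.83% were without overlap, against 10% on average over the splits of the mice. Many genes of a mouse can shift together, so a single split can lie far from that average. The excess was therefore not tested. The number of calls varied widely with the mouse left out, in fits that also held fewer mice. It was 2098 without deficient mouse 1, 155 without deficient mouse 3, and 44, 53 and 99 without wild-type mice 1, 2 and 3; without deficient mouse 2 it was 684. In all 6 of these fits 39 of the 746 genes passed, 35 higher and 4 lower. DESeq2 called 1208 genes.

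**Figure D1:**
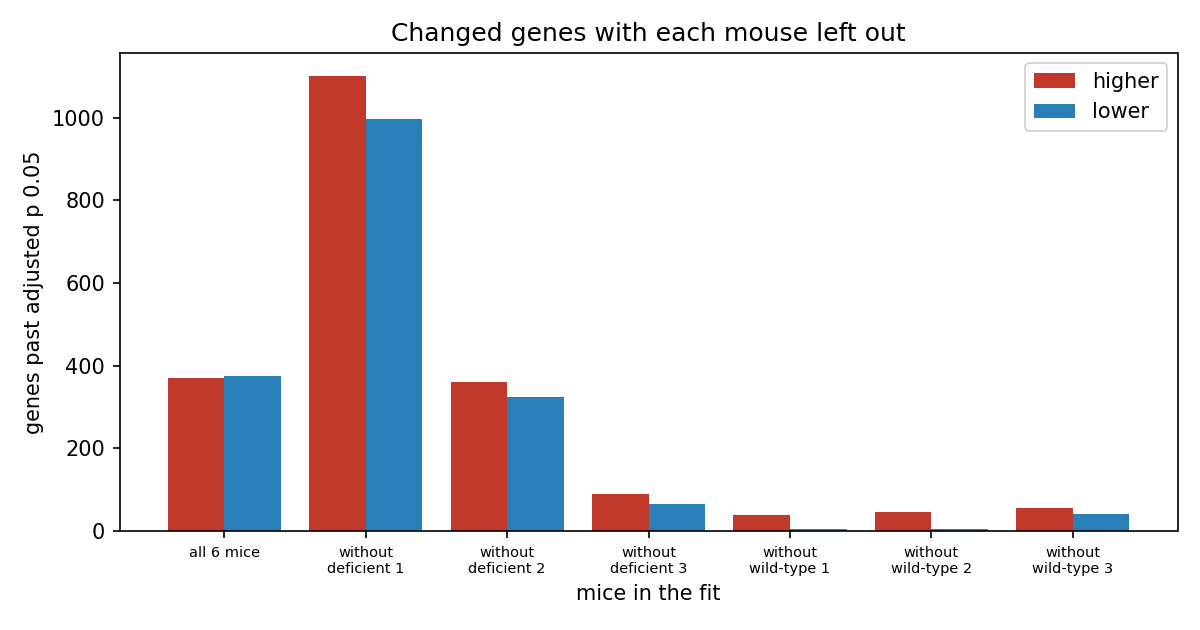
Genes higher (red) and lower (blue) in Kdm5c-deficient brain at an adjusted p under 0.05, with all 6 mice and with each mouse left out in turn. Bars are counts of genes, with 371 higher and 375 lower with all mice. Leaving out a mouse gave from 38 higher and 6 lower (without wild-type mouse 1) to 1101 higher and 997 lower (without deficient mouse 1).

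Other large rises included A830008E24Rik (log2 fold change 3.17), Hsf2bp, a binding partner of heat shock factor 2 known from meiosis (2.72), 4930524B15Rik (2.63), the ammonium transporter gene Rhcg (2.29), skeletal muscle actin Acta1 (2.26), the calcium channel subunit gene Cacng6 (2.12) and the RNA-binding ubiquitin ligase gene Trim71 (2.03). Apart from Gm10800, the falls taken by the same rule were smaller than these rises. The nuclear non-coding RNA Malat1 went from 220.3 ± 53.8 to 90.7 ± 16.6 CPM (SD, n = 3 each), and A930011O12Rik had a log2 fold change of -1.14, Lum, the gene of the matrix protein lumican, -1.13, Stil, a centriole duplication gene, -1.08, and Mpp4 -1.54. Gm14443 (-1.18), Gm17388 (-1.15), 4632427E13Rik (-1.07), Cyp2j12 (-1.07) and Ubap1l (-1.06) completed the falls apart from Gm10800. For Gm10800 there were 0, 3 and 0 reads in deficient mice and 641, 863 and 27 in wild-type mice, a ratio of wild type to deficient of 506 with a 95% exact counting interval of 173 to 2458, and the wild-type mice differed greatly among themselves. Reads of Mpp4 are uncertain because its exons overlap an antisense gene. The call of Mpp4 was lost without scaling of the libraries, and those of Gm10800 and Rhcg with limma-voom.

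Among the 24 genes that the rule takes by size, Pnmt, Zar1, Tex14, A830008E24Rik, Apoc1, Acta1, Trim71 and Robo3 passed the threshold in every fit that left out 1 mouse. The other 16 passed in 1 to 4 of these 6 fits. The adjusted p of the 8 genes that passed in every fit ranged from 0.000125 to 0.00463 by edgeR's quasi-likelihood test with all mice.

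**Figure D2:**
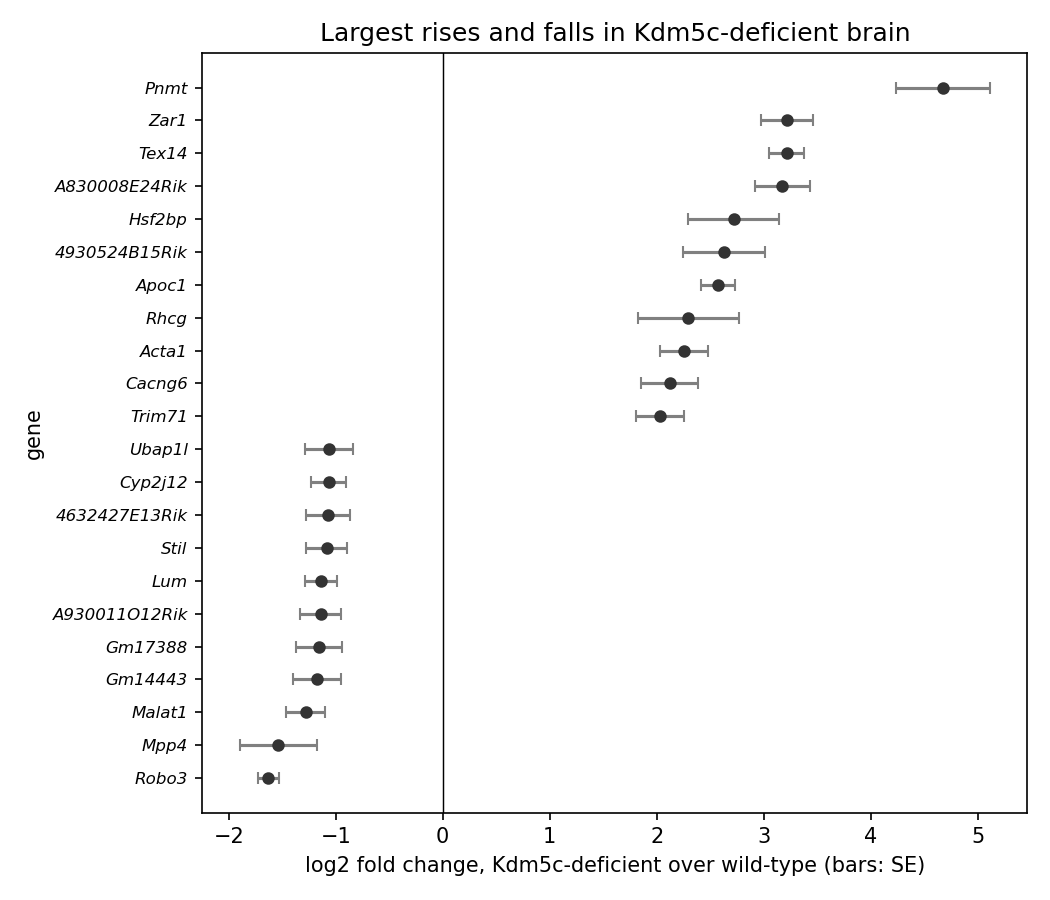
Log2 fold change, deficient over wild-type, with its standard error, for genes among the largest rises and falls, without Gm10800. Among those drawn, Pnmt stands highest at 4.67 and Robo3 lowest at -1.63.

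Of 78 listed genes normally restricted to germ cells, 31 had enough reads to be tested. Among these 31, 10 were higher and 1 was lower, the others not passing, and the median log2 fold change was 0.42. Adjusted over the list alone, 14 were higher and 1 lower. The filter can admit a gene by its reads in a single genotype, so these shares describe detected genes only. With no low-count filter 13 were higher, and the list passed with camera (adjusted p = 2.23e-07). The list passed with camera (adjusted p = 1.06e-11), with an adjusted p of 0.0653 with an estimated correlation. D1Pas1, a germ cell RNA helicase gene, had 32, 35 and 23 reads in deficient mice and 0 in each wild-type mouse, at least 30.5-fold higher against a floor of 3 counts over the group, although its exons overlap an antisense gene. Stk31 rose from 0.145 ± 0.0413 to 1.40 ± 0.625 CPM (SD, n = 3 each), and the wild-type level of Tex14 was 1.01 ± 0.144 CPM (SD, n = 3). The lower gene was Zcwpw1, a histone reader of meiotic cells with a log2 fold change of -0.72 ± 0.12 (SE), chosen after its values were seen; its call was lost in fits that left out a mouse, and its exons overlap an antisense neighbour. The germ cell list was the only one past the threshold by fry. The count of higher members was 3 without any one of the wild-type mice, and 12 without deficient mouse 2. With a filter of at least 5 CPM, 1 member was higher.

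**Figure D3:**
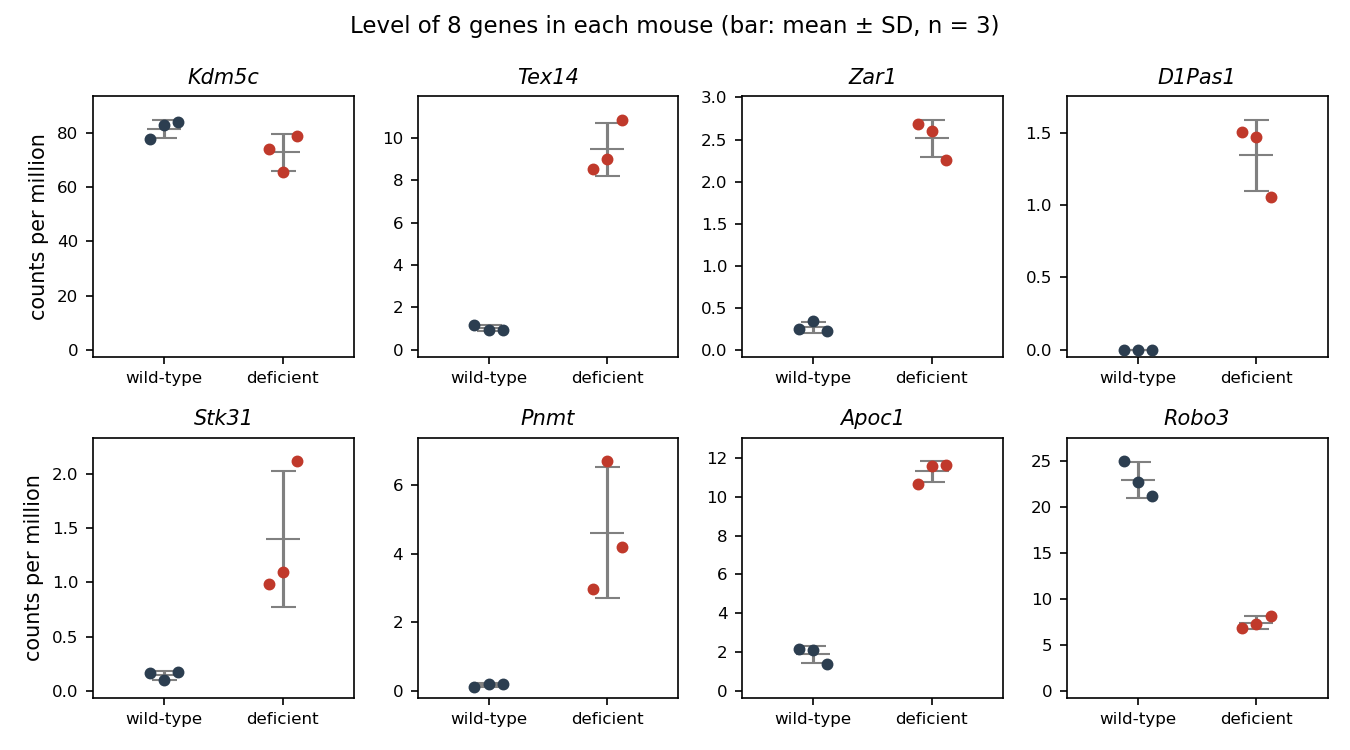
Level in CPM of 8 genes in each mouse, with the mean and SD of each genotype (n = 3). Kdm5c overlaps between genotypes, whereas the 4 germ cell genes, Pnmt and Apoc1 lie higher in every deficient mouse, and Robo3 lies lower.

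Some stress, activity and peptide genes were higher in deficient brain. Of 32 chaperone and stress genes, 6 rose and none fell (11 and 0 adjusted over the list alone), among them Hspa5, the main chaperone of the endoplasmic reticulum (log2 fold change 0.27 ± 0.05, SE), and Calr (0.24 ± 0.05). Hspa1a (1.16) and Hspa1b also rose, but they are near-identical copies, so their reads are uncertain. Of 32 immediate early genes, which respond to neuronal activity, 4 rose (11 higher and 1 lower adjusted over the list alone), Dusp6 (0.36 ± 0.06), Nr4a3 (0.48 ± 0.08), Klf2 (0.53 ± 0.12) and Egr1 (0.43 ± 0.10). The mean deviations of this list were 0.10, -0.01 and 0.20 in deficient and -0.15, -0.21 and 0.06 in wild-type mice, so the genotypes overlapped. Of 30 neuropeptide genes, 4 rose (9 adjusted over the list alone), Pomc, the precursor of opioid and melanocortin peptides (1.29 ± 0.26), Avp (1.20 ± 0.28), Trh (0.73 ± 0.17) and Cartpt (0.63 ± 0.11). Pomc, Avp and Trh are also 3 of the 4 higher members among 24 markers of thalamus and hypothalamus. These 3 lists passed with camera (adjusted p = 7.84e-06, 3.98e-05 and 0.000116), and each had an adjusted p of 0.793 with an estimated correlation. Each of the named calls held in only 1 to 3 of the 6 fits that left out a mouse. Without scaling of the libraries Klf2 and Avp lost theirs, and with GC and length offsets or a filter of at least 5 CPM Trh and Avp did.

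Some genes that act on H3 lysine 4 methylation were lower. The methyltransferase genes Setd1a, Kmt2d and Kmt2b fell, with log2 fold changes of -0.37 ± 0.07, -0.43 ± 0.09 and -0.35 ± 0.08 (SE), and Kmt2c had -0.32 ± 0.09 without passing. Of 28 tested members 3 fell and none rose (6 lower adjusted over the list alone). The camera test gave an adjusted p of 0.014, with an adjusted p of 0.793 with an estimated correlation, and the list lost its call without deficient mouse 2 and with GC and length offsets. Exons of Setd1a overlap those of another gene on the same strand, so its reads are uncertain. Each of these 3 calls held in 2 of the 6 fits that left out a mouse, and that of Kmt2d was lost with GC and length offsets. Ribosomal protein genes passed as a list with none of 75 members past the threshold, at a median log2 fold change of 0.11 (adjusted p = 0.00462 with camera, 0.793 with an estimated correlation), and lost the call in the same fits. Their mean deviations, -0.04, 0.12 and 0.01 in deficient and 0.03, -0.09 and -0.02 in wild-type mice, overlapped between genotypes.

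Regional markers differed between mice. Cerebellar markers were lower in deficient mice as a list, with 21 of 23 members negative and none called (camera, adjusted p = 3.98e-05, with an adjusted p of 0.793 with an estimated correlation). Deficient mouse 2 was lowest: the mean log2 deviation of these genes was 0.40, -1.89 and 0.04 in the deficient mice and 0.40, 0.45 and 0.60 in the wild-type mice. Without this mouse the list still passed with camera in the same direction (adjusted p = 2.19e-06). That p-value rests on the preset correlation, far below the 0.836 estimated for this list with all mice. It therefore cannot decide whether the fall holds without deficient mouse 2. Deficient mouse 1 was level with wild-type mouse 1, both at 0.40, so the mean deviations of the remaining mice did not separate the genotypes. Gabra6, a receptor gene of cerebellar granule cells chosen after its values were seen, had 131 reads in deficient mouse 2 and from 1937 to 3429 in the others. Among 15 markers of olfactory bulb and newborn neurons 2 rose (2 adjusted over the list alone), Sox11 (log2 fold change 0.51 ± 0.10, SE) and Trh. The mean deviations were -0.14, -0.08 and 0.77 in deficient and -0.25, -0.28 and -0.02 in wild-type mice, so the genotypes overlapped. That list had an adjusted p of 0.0029 by camera, with an adjusted p of 0.793 with an estimated correlation, and lost its call without deficient mouse 3. The low cerebellar level of deficient mouse 2 stands beside every list described here. Without deficient mouse 2, 13 lists passed, 10 of them among the 14 that passed with all mice.

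Some oligodendrocyte markers were lower and some microglial markers higher in deficient brain. The tetraspanin gene Tspan2 went from 209 ± 17.4 to 142 ± 11.5 CPM (SD, n = 3 each), and Trf and Ugt8a fell with log2 fold changes of -0.49 and -0.32. Of 26 members 4 were lower (7 adjusted over the list alone), with an adjusted p of 4.05e-05 by camera and an adjusted p of 0.793 with an estimated correlation. The mean deviations were 0.08, -0.15 and -0.22 in deficient and 0.11, 0.16 and 0.02 in wild-type mice, so deficient mouse 1 lay within the wild-type range. Reads of Trf are uncertain because its exons overlap another gene on the same strand. Of 23 microglial markers, Siglech (0.66 ± 0.10, SE) and Fcrls (0.80 ± 0.14) rose and none fell (7 higher adjusted over the list alone), with an adjusted p of 9.1e-05 by camera and an adjusted p of 0.793 with an estimated correlation. Among markers of excitatory neurons Spink8 rose (1 of 21 members, with 8 higher and 2 lower adjusted over the list alone), and Gja1, the astrocyte gap junction gene, rose among 22 astrocyte markers (4 higher adjusted over the list alone). A single call in lists of this size is near the 4.93% changed over all tested genes. Endothelial and ependymal markers had no member called, at medians of 0.12 and 0.22. These 4 lists passed with camera, at adjusted p from 0.0029 for excitatory neurons to 0.0462 for astrocytes, with adjusted p of 0.793 or 0.832 with an estimated correlation. The genotypes overlapped in the mean deviations of excitatory neuron markers, at -0.08, 0.27 and 0.14 in deficient and -0.07, -0.23 and -0.03 in wild-type mice, and of astrocyte markers, at 0.14, -0.12 and 0.10 against -0.02, -0.07 and -0.03. The excitatory neuron list lost its call without deficient mouse 2, the endothelial list without deficient mouse 1 or wild-type mouse 2, the ependymal list without deficient mouse 1 or 2 or wild-type mouse 3, and the astrocyte list without deficient mouse 1 or 3 or wild-type mouse 2. With a filter of at least 5 CPM the astrocyte list lost its call and the ependymal list turned its direction (camera, adjusted p = 0.0514 and 0.99). The named calls each held in only 1 to 4 of the 6 fits that left out a mouse. Those of Spink8 and Ugt8a were also lost with GC and length offsets, and that of Spink8 with limma-voom.

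**Figure D4:**
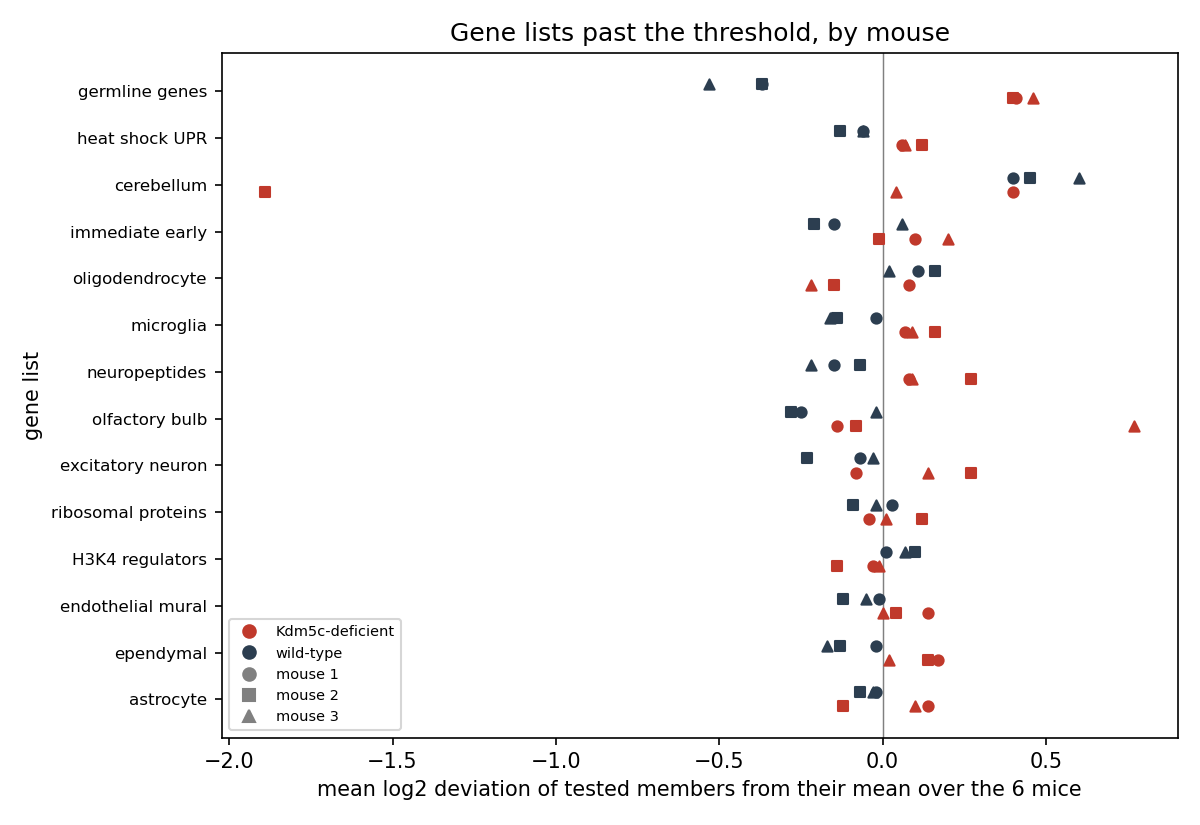
Mean log2 deviation of the tested members of each list past the threshold from their mean over the 6 mice, for deficient (red) and wild-type (blue) mice, with symbols for mouse number. The germ cell list separates the genotypes, from 0.40 to 0.46 against -0.53 to -0.37. Other lists do so by less, such as chaperone and stress genes, from 0.06 to 0.12 against -0.13 to -0.06. All lists drawn had passed the test of genotype, so separation adds no support. The cerebellar list has 1 deficient mouse at -1.89.

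In total 14 of 39 tested lists passed with camera, 11 higher and 3 lower, and none passed with an estimated correlation. Lists that did not pass also held changed genes, beside a share of 4.93% changed over all tested genes. The counts below were not tested against that share and do not by themselves set a list apart. Of 63 axon guidance genes 2 rose and 4 fell (5 and 8 adjusted over the list alone), with the ligand gene Ntn3, whose exons overlap a neighbour on the same strand, at 1.24 ± 0.09 (SE) and the receptor genes Unc5b and Epha8 at -0.57 ± 0.10 and -0.83 ± 0.18. Of 61 ion channel genes 1 rose and 3 fell (5 and 11 adjusted over the list alone): the sodium channel genes Scn4b (-0.48) and Scn1a (-0.33) and the calcium channel gene Cacna1i (-0.24) fell, and Scn3b (0.41) rose. With GC and length offsets Scn1a, Cacna1i and Scn3b lost their calls, and Scn3b also lost its call with upper quartile scaling, limma-voom and a filter of at least 5 CPM. Of 41 vesicle release genes 3 rose and none fell (8 higher and 5 lower adjusted over the list alone), Doc2a (0.74), Syt5 (0.64) and Rab3b (0.34), with an adjusted p of 0.13 by camera, and exons of Doc2a overlap an antisense gene. Ftx, a non-coding RNA of the X inactivation centre, fell by 0.96 ± 0.14 (SE) on the log2 scale, 1 of 15 genes listed as escaping X inactivation, none of which rose (1 higher and 2 lower adjusted over the list alone). Markers of thalamus and hypothalamus had a median of -0.005 and a mean of 0.229, so that their median and test differed in sign, and of 24 members 4 rose (6 adjusted over the list alone), Pomc, Avp, Trh and Baiap3 (0.76 ± 0.10, SE), with an adjusted p of 0.0856 by camera. Of the genes named here from these lists, Ntn3 passed in all 6 fits that left out a mouse, as did Robo3, another of the axon guidance genes that fell. The others passed in 2 to 5 of these fits.

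Changed genes were spread over the chromosomes. Chromosome X held 28 changed genes of 527 tested (5.31%), and the share over all tested genes was 4.93%. No chromosome stood apart by two-sided Fisher's exact tests (smallest adjusted p = 0.671), and 1 chromosome had an unadjusted p under 0.05. None of 39 tested genes within 5 Mb of Kdm5c was changed, against 28 of 487 others on the X chromosome (Fisher's exact test, p = 0.254), which at this number of genes does not show a difference.

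The authors' deposited table gave 2932 genes with an unadjusted p under 0.05, and 1033 after Benjamini-Hochberg adjustment of the authors' deposited p-values. All 746 genes called here had the same direction there, and 673 of them were among those 1033 genes of the authors' deposited table. Both sets of values come from the same counts.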

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

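Offsets for GC content and length were chosen after the data were seen. The count of 746 changed genes (371 higher, 375 lower) became 1121 (558 and 563) with no low-count filter, 1208 (611 and 597) with DESeq2, 1792 (857 and 935) at adjusted p under 0.1, and 270 (174 and 96) with a 1.5-fold minimum, the last 2 by construction. Leaving out 1 mouse gave 44 to 2098 changed genes, 38 to 1101 higher and 6 to 997 lower. In these fits 2496 to 4593 genes had an unadjusted p under 0.05 by edgeR's quasi-likelihood test. The estimated common variation between mice of a genotype was 6.76% without deficient mouse 1 and 5.59% without deficient mouse 2. It was 8.36 to 8.84% in the other fits and 7.82% with all mice. Fewer samples were fitted, and the cause of the wide range was not tested further. Median-ratio and upper quartile scaling, no scaling, a 5 CPM filter, limma-voom and GC and length offsets gave 570 to 762, and the offsets kept 609 of the 746 genes. Deviations of same-numbered mice from their genotype means correlated at -0.06, -0.06 and 0.14. Deficient mice 1 and 2 correlated best with a wild-type mouse of another number. Deficient mouse 3 correlated best with its own number, at 0.14 against at most -0.03. So few mice cannot show whether the numbers pair them. The replicate block gave 58 changed genes (49 higher, 9 lower) and 3 higher germ cell genes. Higher germ cell genes numbered 1 with the 5 CPM filter, by removal of low genes, and 3 to 12 without 1 mouse. The 14 lists became 0 with an estimated correlation and 1 with fry, and 12 to 18 otherwise; all 14 passed under every scaling, and GC and length offsets ended the ribosomal protein and H3K4 lists. The ependymal list turned its direction with the 5 CPM filter (adjusted p = 0.99 by camera), and Kdm5d ran from log2 -0.34 to 0.18 without 1 mouse, turning without wild-type mouse 2; their causes were not tested. Kdm5c stayed lower and short of the threshold in every alternative, at log2 -0.23 to -0.09. No chromosome passed at other thresholds, and p near Kdm5c ran from 0.0666 to 0.405. Genes of under 1.5-fold change are limited by depth and number of mice.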

Other observations

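The muscle gene list, the GC and length offsets, the size of small changes with them and the rise over wild type of spermatid genes were tests chosen only after results had been seen, and so were the genes named here outside the rule. The muscle list held genes of the sarcomere, of skeletal muscle metabolism and others, such as the calcium channel subunit gene Cacng6. Of its 48 tested genes, 9 rose, 1 fell and 38 did not pass, with a median log2 fold change of 0.17 and no test of the list. Acta1 and Cacng6, described above, are among the 9. Pgam2, the muscle phosphoglycerate mutase gene, rose by 1.97 ± 0.17 (SE), while Ttn, which encodes titin, had -1.02 ± 0.22, passed in 1 of the 6 fits that left out a mouse and lost its call with GC and length offsets. Among nuclear non-coding RNAs Meg3 (-0.92 ± 0.12), Snhg11 (-0.86 ± 0.13), Miat (-0.65 ± 0.11) and Mirg (-0.76 ± 0.12) fell, each losing its call in at least 1 of those fits, while Neat1 had 0.00 ± 0.12 and Rian -0.07 ± 0.05, neither past the threshold. As a class, 22 of 661 long non-coding genes fell (3.33%) against 344 of 14236 protein-coding genes (2.42%), which did not differ past the threshold (two-sided Fisher's exact test, p = 0.155).

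The rise of germ cell genes was weighed against RNA from testis. The 8 spermatid genes had 207 reads in the deficient libraries, more than the 90 of D1Pas1, which a bound set beforehand would have read as testis RNA; that bound was wrong, because Oaz3, whose exons overlap those of Tdrkh, gave 189 reads in deficient and 220 in wild-type brain. The other 7 genes had 18 and 17 reads. Judged by the rise over wild type, the summed CPM of the 8 genes differed by -0.40 ± 0.32 (SE), while D1Pas1 rose by 1.34 ± 0.14 (SE), which argues against spermatids as the source. With GC and length offsets 10 of 10 germ cell calls passed, at a median log2 change of 2.96 before and after. This argues only against the smooth trend that the offsets removed as the whole cause. Such offsets could hardly end changes of this size, since changes under 1.5-fold moved only from a median of 0.36 to 0.34. Uneven recovery particular to single genes was not tested. Loss of Kdm5c, named by the design, stays open as a hypothesis and may raise these genes, and other technical sources were not tested.

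For the muscle genes, 9 abundant skeletal muscle genes such as Ckm and Mylpf together rose by 0.526 ± 0.247 CPM (SE), under the 3.29 ± 0.508 CPM of Acta1 alone, which argues against muscle tissue in the samples. With the offsets the calls of 9 of 9 higher genes passed, at a median log2 change of 1.54 before and 1.52 after. Here too the offsets could hardly have ended changes of this size. A difference that follows the genotype may underlie the rise and was not tested further.

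For the many changes under 1.5-fold, the GC and length offsets kept 361 of 476 calls, 75.8% with an exact 95% interval of 71.7 to 79.6%, which spans the bound of 75% set beforehand. The interval treats genes as independent, although all were measured in the same mice, so it can be too narrow. The share kept does not decide the question. All 476 kept their direction and the median absolute log2 change went from 0.36 to 0.34 (median SE 0.07), which argues against the trend that the offsets removed as the whole cause of these changes. For the 115 lost calls it went from 0.31 to 0.26 at an SE of 0.07, so that calls near the threshold ended (median adjusted p by edgeR's quasi-likelihood test 0.0442 before and 0.0601 after), and a part played by uneven recovery cannot be told apart there. A different share of cerebellum is a candidate explanation. The median absolute within-genotype correlation of these genes with the cerebellar marker mean was 0.645. This was above the 0.602 of the 95th percentile of 1000 sets matched on mean count. For oligodendrocyte markers it was 0.411, under the matched median of 0.506. The cerebellar marker mean departed most in deficient mouse 2 (-1.89), so the correlation rests largely on 1 mouse and cannot decide the question. In deficient mouse 1 that mean was 0.40, level with wild-type mouse 1. Without deficient mouse 2, which had the low cerebellar markers, 327 of the 476 calls (68.7%) still passed, and the genotype itself stays open.

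Of the 10 splits of the 6 mice into 3 and 3, 1, the real one, called as many as 746 genes, and the highest of the others called 2; 10 splits are too few for a share under 0.05. A test of clustering on chromosome 11 had been planned and was not run, because its share of changed genes (4.4%) was not above that of all tested genes (4.93%).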
